A study of Mus musculus with 24 samples.

How the data were processed

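The study measured messenger RNA in 4 epithelial cell populations sorted from the small-intestinal crypts of 6 male C57BL/6 mice (littermates, per the labels) that carry the Lgr5-EGFP reporter. Per the labels' protocols, 3 mice received 7.5 µg of neuregulin 1 (NRG1, a growth factor that binds the ErbB3 and ErbB4 receptors) by intraperitoneal injection every 12 h for 5 days, 3 received the vehicle (PBS), and tissue was taken on day 6. Per the labels, replicates 1 and 2 of each treatment were 15 weeks old and replicate 3 was 11 weeks old. Crypt cells negative for CD31, CD45 and propidium iodide were sorted by EGFP and CD24 into Lgr5high (crypt base columnar stem cells), Lgr5med (immediate progenitors), Lgr5low (subsequent progenitors) and Lgr5neg (differentiated cells) populations. That gave 24 libraries in 8 groups of 3. Each mouse gave 1 library per population, as read from the shared first part of each sample's description label. Libraries were made from 15 ng of RNA with a NuGEN Ovation kit and sequenced as single reads of 76 nt, per the labels' protocols.

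Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on GRCm38. The versions of these tools, the annotation release and the strand setting of the counting were not given in the sources used here. The deposited table held counts of reads per gene symbol for 43280 symbols, as whole numbers that the authors had not normalised, and all columns belonged to a sample. Of the symbols, 39374 matched the GENCODE vM21 annotation of GRCm38 directly, 947 matched through an older symbol and 2959 did not match. Coordinates are on GRCm38 from that annotation.

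Total counts per library lay between 11176264 and 23343499 with a median of 19660148. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 37.6% to 62.4% of the counts, which left 6192378 to 12549810 counts for other genes. A count of 3, used as the floor that a count of 0 allows, was worth 0.129 to 0.268 CPM (edgeR's unit of counts relative to the library total). Floors cover counting error only, and the reads carry no molecular identifiers. The 95% interval of a ratio of medians comes from 2000 bootstrap resamples of the genes. Of all symbols, 16628 had a count of 0 in all libraries. No library was left out.

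Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust), after TMM scaling and edgeR's filter on low counts (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another tool is named. NRG1 was compared with PBS within each population on 6 libraries. The populations were compared with each other on the 12 PBS libraries in 1 model. Whether the NRG1 response of Lgr5high cells differed from that of each other population was tested as an interaction over all 24 libraries. CPM values are means ± SD of 3 libraries, scaled by TMM within the libraries of the comparison they are printed with, so levels of the same gene differ between comparisons. Plots of single libraries use CPM scaled over all 24, with a prior count of 2 where they are on a log2 scale.

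The 28 gene lists (617 entries, 602 distinct genes) covered crypt base columnar stem cell markers, Wnt targets, G2/M and mitosis, S phase and DNA replication, ribosome biogenesis, ErbB receptors and ligands, ERK feedback genes, the Notch pathway, regenerative and YAP-associated genes, enterocyte, goblet, Paneth, enteroendocrine and tuft markers, and immune, endothelial, mesenchymal, neural and erythroid markers. They also covered dissociation and immediate-early genes, cholesterol biosynthesis, fatty acid oxidation, glycolysis and hypoxia, the unfolded protein response, antigen presentation and interferon response, antimicrobial genes, p53 targets, and mitochondrially encoded genes. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 measured genes. Each test was repeated with an estimated correlation and with fry, which ended the calls of 108 and 59 of the 170 list results compared. The 170 include lists that were not called and so had no call to lose. No list called in a comparison of NRG1 with PBS kept its call with the estimated correlation. Shares of the gene lists in each library's counts outside mitochondrial ribosomal RNA were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

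The designs, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named, per comparison, the 8 largest rises and the 8 largest falls (5 for populations and interactions) among called genes with an average log2 CPM of at least 2 and no overlap between the groups, leaving out predicted genes and pseudogenes. It also named up to 2 risen and 2 fallen members of each list, or the 2 most abundant members as values where none passed, and always Lgr5, Olfm4, Ascl2, Mki67, Ccnd1, Myc, Egfr, Erbb2 and Erbb3.

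Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM in 3 libraries, an adjusted p under 0.10, a replicate block, age as a block of 2 levels, all 24 libraries in 1 model, limma voom with the mouse as a random effect, only the libraries compared, and each library left out in turn. Counts thinned to the smallest library, counts without mitochondrial ribosomal RNA, and a correction for GC content and gene length (a loess trend of span 0.5), with and without the block, were added after the data had been seen. All of these were run for counts of genes where they apply. Named genes were run with the DESeq2 size factors and test, the block and each library left out, and lists with the size factors, the block, each library left out and the alternatives added later. To ask whether replicate numbers pair the libraries, deviations from the group means were correlated between the NRG1 and PBS libraries of the same number. These correlations were 0.109 to 0.267 in Lgr5med, 0.174 to 0.236 in Lgr5low and 0.201 to 0.306 in Lgr5neg cells, all over 0.1, so blocked results are printed beside the main ones there where they differ. In comparisons of populations and in interactions the number marks the mouse. Libraries of 1 PBS mouse correlated at 0.0341 to 0.273 and those of different PBS mice at -0.225 to 0.0524.

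The tests were run on simulated counts with 200 genes changed, a list of 25 more raised 1.5-fold, and the real libraries' sizes. Means were those of each population, except that the comparisons of populations used 1 mean over all populations. No effect of the mouse was simulated, so the rates for the population and interaction tests come from a simpler setting than the data. Of genes changed 2-fold, 59% were recovered in the Lgr5high comparison of NRG1 with PBS (13322 genes), 69% in Lgr5med (13394), 57% in Lgr5low (13326) and 51% in Lgr5neg (11908). The 4 comparisons of populations (14203 genes) recovered 53% to 63% of them, and the 3 interactions (15045 genes) 25% to 28%. Of genes changed 4-fold, the treatment comparisons recovered 82% to 93%, the population comparisons 75% to 81% and the interactions 64% to 71%. Of the simulated calls, false ones made up 12.1% in Lgr5high (22 of 182), 4.76% in Lgr5med, 5.62% in Lgr5low and 9.33% in Lgr5neg cells, 1.42% to 6% in the population comparisons and 1% to 7% in the interactions, against the 5% aimed for.

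Counting that can split reads between near-identical copies makes the values of H3f3a, Gapdh, ribosomal protein genes such as Rpl10a and Rps28, the Defa and Gm15284 defensin family, Gsdmc2, Gsdmc4, Apol10a and Mt2 uncertain. The strand setting was not stated, so reads from Rab26os and its sense partner cannot be separated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and sequence matches were searched with blastn 2.17.0.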

Results

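RNA was sequenced from 4 sorted crypt populations of 3 NRG1-treated and 3 PBS-treated mice, as 24 libraries in 8 groups of 3. By the names given to the sorted gates, the populations run from Lgr5high stem cells through Lgr5med and Lgr5low progenitors to Lgr5neg differentiated cells. Goblet, enteroendocrine and Paneth markers did not rise steadily along that order, as given below. Total counts per library ranged from 11176264 to 23343499, and 11624 to 13876 genes per library had 10 or more counts. The lowest totals were those of the Lgr5low NRG1 libraries of replicates 1 (11176264) and 3 (12549951).

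The first question was how the sorted populations of untreated (PBS) mice differed from each other. Of 14203 genes tested, 1302 differed between Lgr5high and Lgr5med cells (347 higher and 955 lower in Lgr5high). Lgr5 itself, the gene whose reporter set the gates, stood at 171 ± 62.0 CPM in Lgr5high and 28.8 ± 19.9 CPM in Lgr5med cells (SD, n = 3; log2 difference 2.57, SE 0.482, adjusted p = 0.0107; chromosome 10, 115450311 to 115587780). Without Lgr5med PBS replicate 3 its adjusted p was 0.0516. Olfm4, a stem cell marker, was at 2225 ± 422 against 747 ± 348 CPM (log2 difference 1.57, SE 0.264, adjusted p = 0.00158). Ascl2, a transcription factor of crypt base stem cells, differed by 1.35 (SE 0.210, adjusted p = 0.000534). Zg16, a goblet cell lectin, was 28.1-fold lower in Lgr5high than in Lgr5med cells, at 34.6 ± 27.2 against 973 ± 525 CPM (log2 difference -4.81, SE 0.728, adjusted p = 0.00425). Alpi, the brush border alkaline phosphatase, was lower by a log2 difference of -2.47 (adjusted p = 0.00167). Cdkn1a, which encodes the cell cycle inhibitor p21, was lower by -1.91. Mki67, a proliferation marker, did not pass (log2 difference 0.22, adjusted p = 0.571). The count of genes was 679 without Lgr5high PBS replicate 1, 742 without Lgr5high PBS replicate 3, 668 without Lgr5med PBS replicate 2 and 634 without Lgr5med PBS replicate 3.

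Stem cell markers were higher in Lgr5high than in Lgr5med cells for 24 of 28 genes (28 adjusted over the list alone; camera adjusted p = 3.77e-32, adjusted p = 0.0732 with an estimated correlation), with a median log2 difference of 1.17. Wnt targets were higher for 12 of 22 genes (16 adjusted over the list alone; 1.31e-15, and 0.0732 with an estimated correlation). Goblet markers were lower for 16 of 18 genes and higher for 1 (17 lower and 1 higher adjusted over the list alone; 2.87e-18, and 0.125 with an estimated correlation). The gene that was higher carries the deposited symbol Clca1, which cannot be tied to 1 gene because the deposited symbol Clca3 (log2 difference -4.095, adjusted p = 0.0137) leads to the same gene of the annotation. The call of Clca1 ended without Lgr5high PBS replicates 1 (0.124) or 3 (0.161) or Lgr5med PBS replicates 2 (0.129) or 3 (0.1465), with 0.0109 to 0.161 over the alternatives run for it, and that of Clca3 without Lgr5high PBS replicate 3 (0.0702), with 7.27e-08 to 0.0702. Enteroendocrine markers were lower for 13 of 24 genes (23 adjusted over the list alone; 4.36e-18, and 0.125 with an estimated correlation). Enterocyte markers were lower for 9 of 30 genes (16 adjusted over the list alone; 9.84e-11, and 0.303 with an estimated correlation). Antimicrobial genes were lower for 9 of 17, cholesterol biosynthesis genes for 12 of 25 and unfolded protein response genes for 8 of 22 (9, 15 and 14 adjusted over the list alone), with camera adjusted p = 2.21e-08, 3.91e-08 and 1.2e-07, and 0.0732, 0.303 and 0.324 with an estimated correlation. S phase genes had a median of 0.27, with none of 29 passing (0 adjusted over the list alone; camera adjusted p = 0.0013, and 0.303 with an estimated correlation). G2/M genes were not called (median 0.12, adjusted p = 0.0592). Regenerative genes (median -0.45, 2 of 12 lower, 4 lower and 1 higher adjusted over the list alone; 0.0341, and 0.455 with an estimated correlation) lost the call with the mouse as a replicate block (0.0597) and without Lgr5high PBS replicate 2 (0.489) or Lgr5med PBS replicates 1 (0.0856), 2 (0.235) or 3 (0.197), within 0.0122 to 0.489 over the alternatives run for it.

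From Lgr5med to Lgr5low cells 1078 genes differed (284 higher and 794 lower in Lgr5med). Enterocyte genes were among those that differed. Apob, the structural protein of chylomicrons, was at 344 ± 26.6 CPM in Lgr5med and 1037 ± 262 CPM in Lgr5low cells (n = 3; log2 difference -1.59, SE 0.177, adjusted p = 8.88e-05; chromosome 12, 7977648 to 8016835). Anpep, a brush border peptidase, was at 260 ± 35.7 against 871 ± 289 CPM. Axin2, a feedback inhibitor and target of Wnt signalling, was higher in Lgr5med cells at 122 ± 32.0 against 52.7 ± 2.00 CPM (log2 difference 1.21, SE 0.161, adjusted p = 0.000221). Olfm4 was higher by 1.71 (SE 0.266, adjusted p = 0.0012) and Myc, a growth-promoting transcription factor, by 1.03. Lgr5 did not pass (1.78, SE 0.492, adjusted p = 0.0642). The count of genes was 464 without Lgr5med PBS replicate 1, 703 without Lgr5med PBS replicate 2, 672 without Lgr5low PBS replicate 1 and 656 without Lgr5low PBS replicate 3.

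Enterocyte markers were lower in Lgr5med than in Lgr5low cells for 25 of 30 genes (28 adjusted over the list alone; camera adjusted p = 2.31e-37, and 0.0589 with an estimated correlation). Stem cell markers were higher for 22 of 28 genes (25 adjusted over the list alone; 1.4e-30), Wnt targets for 9 of 22 (15; 1.32e-13), ribosome biogenesis genes for 8 of 26 (17; 8.3e-11) and S phase genes for 7 of 29 (16; 1.2e-09), each at 0.0589 with an estimated correlation. G2/M genes had a median of 0.23 with none of 28 passing (camera adjusted p = 0.000429, and 0.284 with an estimated correlation). Fatty acid oxidation genes were lower for 7 of 26 (9 adjusted over the list alone; 3.345e-06, and 0.284 with an estimated correlation). Goblet markers were not called (adjusted p = 0.0967), and Muc2, the main intestinal mucin, had a log2 difference of -0.77 (adjusted p = 0.468).

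The step to Lgr5neg cells was the largest. Lgr5low and Lgr5neg cells differed in 7931 genes (4344 higher and 3587 lower in Lgr5low), and Lgr5high and Lgr5neg cells in 9576 (5034 higher and 4542 lower in Lgr5high). Mki67 was at 664 ± 79.1 CPM in Lgr5low and 36.0 ± 12.3 CPM in Lgr5neg cells (n = 3; log2 difference 4.21, SE 0.221, adjusted p = 2.17e-11; chromosome 7, 135689784 to 135716361). All 28 G2/M genes and 28 of 29 S phase genes were higher in Lgr5low cells (camera adjusted p = 1.13e-58 and 4.89e-31, and 0.00402 and 0.00638 with an estimated correlation), as were all 26 ribosome biogenesis genes (8.52e-17, and 0.0238). Enterocyte markers were lower for 29 of 30 genes (3.37e-19, and 0.158 with an estimated correlation). Reg3b, an antimicrobial lectin, was at 342 ± 77.1 CPM in Lgr5low and 5618 ± 347 CPM in Lgr5neg cells (log2 difference -4.04, SE 0.266, adjusted p = 8.57e-10). Secretory lineage markers were higher in Lgr5low than in Lgr5neg cells, at 15 of 18 goblet genes (0.0019), 17 of 24 enteroendocrine genes (0.00785) and 15 of 20 Paneth genes (0.0161), with adjusted p = 0.524, 0.524 and 0.570 with an estimated correlation. Against Lgr5high cells, goblet and enteroendocrine markers showed no such difference (camera adjusted p = 0.644 and 0.683). Immune markers were lower in Lgr5low cells for 14 of 15 genes (median -6.095, camera adjusted p = 6.75e-08, and 0.0894 with an estimated correlation). Gzmb, a granzyme of cytotoxic lymphocytes, stood at 33.0 ± 12.2 CPM in Lgr5neg and 0.147 ± 0.0682 CPM in Lgr5low cells. Endothelial markers were not called in any of the 4 comparisons of populations, with camera adjusted p = 0.878 for Lgr5high against Lgr5neg. Adjusted over the list alone, the counts were 18 for enteroendocrine and 17 for Paneth genes and as given for the other lists. From Lgr5high to Lgr5neg cells, stem cell markers were higher for 26 of 28 genes (camera adjusted p = 1.39e-23, and 0.109 with an estimated correlation) and Wnt targets for 20 of 22 (4.27e-13, and 0.0988).

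Of the receptors that bind NRG1, Erbb4 had 2 counts over all 24 libraries together (it falls outside the rule for named genes and was chosen after its values were seen), while Erbb3 had counts in every library. Erbb3, which encodes a receptor that binds NRG1, was lower in Lgr5low than in Lgr5neg PBS cells, at 159 ± 17.3 against 379 ± 40.0 CPM (n = 3; log2 difference -1.26, SE 0.142, adjusted p = 3.88e-07; chromosome 10, 128567523 to 128589652). Erbb2, its signalling partner, differed in the same direction by -1.13. Egfr went the other way, at 46.6 ± 2.48 against 27.7 ± 3.00 CPM (log2 difference 0.75, SE 0.137, adjusted p = 0.000114). Erbb3 did not differ detectably between Lgr5high and Lgr5med cells (0.27, adjusted p = 0.280).

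**Figure D1:**
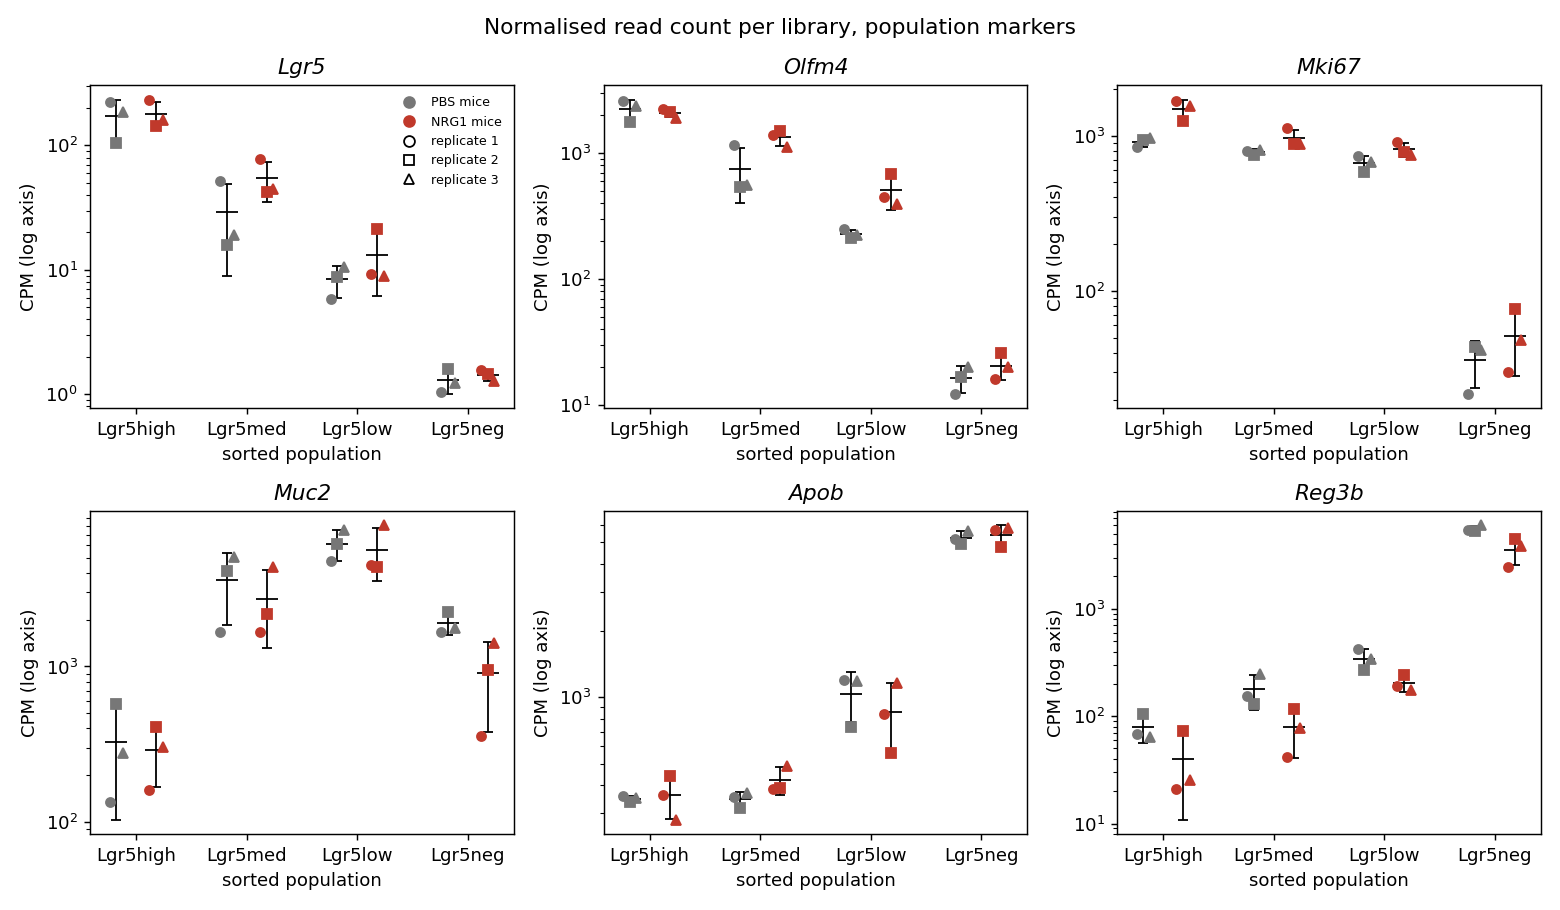
Normalised read count (CPM over all 24 libraries, log axis) of 6 genes in each sorted population; points are libraries (shape gives the replicate, grey PBS, red NRG1) and black bars the mean ± SD of 3 libraries. Lgr5 and Olfm4 decline from Lgr5high to Lgr5neg cells, Muc2 is highest in the Lgr5med and Lgr5low progenitors, and Apob and Reg3b are highest in Lgr5neg cells.

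The second question was how the stem cells of mice given NRG1 for 5 days differed from those of PBS mice. A difference in library preparation that the labels do not record cannot be told apart from NRG1 in any comparison of NRG1 with PBS. Outside Lgr5high cells, counts of mt-Rnr1 per 100 mt-Rnr2 lay higher in all NRG1 than in all PBS libraries of each population. In Lgr5high cells PBS replicate 3 (42.9) lay among the NRG1 values of 38.6 to 51.6. In Lgr5high cells 976 of 13322 genes changed (423 higher and 553 lower), 53 of the rises and 112 of the falls by more than 2-fold. Of the 976 genes, 969 had no overlap between the groups, and 27.4% of all genes tested had none, where chance gives 10%. The largest fall among the named genes was in Ung, a uracil-DNA glycosylase of base excision repair, which was 6.46-fold lower at 12.9 ± 1.30 against 83.6 ± 20.3 CPM (NRG1 against PBS, n = 3; log2 change -2.69, SE 0.171, adjusted p = 1.71e-06; chromosome 5, 114130386 to 114139323). E2f1, a transcription factor that starts S phase, fell from 19.4 ± 3.76 to 5.52 ± 1.53 CPM (-1.82, SE 0.211, adjusted p = 0.000229). Mcm6, a subunit of the replicative helicase, fell from 135 ± 19.8 to 61.2 ± 6.95 CPM (-1.14, SE 0.129, adjusted p = 0.000183). Mitotic genes rose. Cdc20, an activator of the anaphase-promoting complex, went from 30.4 ± 5.88 to 76.8 ± 6.12 CPM (1.34, SE 0.140, adjusted p = 9.11e-05; chromosome 4, 118432901 to 118437352), and Cenpa, the centromeric histone, from 34.9 ± 5.54 to 82.9 ± 4.69 CPM (1.25, SE 0.129, adjusted p = 9.11e-05; chromosome 5, 30666777 to 30674830). Mki67 rose from 1100 ± 76.2 to 1803 ± 247 CPM (0.71, adjusted p = 0.00452). Pik3r3, a regulatory subunit of PI3 kinase, rose by 1.63 (SE 0.211, adjusted p = 0.000401). The count of genes was 491 without PBS replicate 2, 579 without NRG1 replicate 1, 547 without NRG1 replicate 2 and 563 without NRG1 replicate 3, and 480 with all 24 libraries in 1 model. With the replicate number as a block it was 1229.

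**Figure D2:**
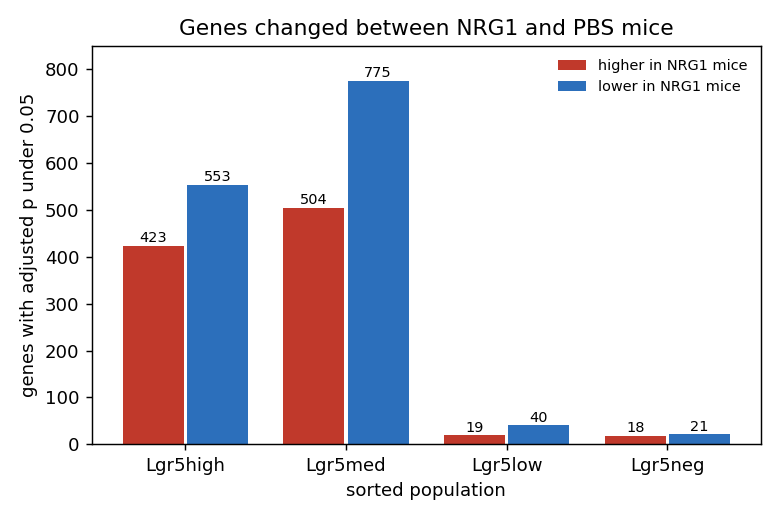
Number of genes with an adjusted p under 0.05 in each comparison of NRG1 with PBS (edgeR), split into genes higher and lower under NRG1. The bars reach 976 genes in Lgr5high, 1279 in Lgr5med, 59 in Lgr5low and 39 in Lgr5neg cells.

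The identity genes of stem cells did not change detectably in Lgr5high cells. The log2 change was 0.07 for Lgr5 (adjusted p = 0.938), -0.08 for Olfm4 (0.797) and 0.03 for Ascl2 (0.940), and none of 28 stem cell markers passed (camera adjusted p = 0.443). Erbb3 rose from 189 ± 26.3 to 270 ± 23.4 CPM (0.52, SE 0.127, adjusted p = 0.0205), while Egfr (0.17, adjusted p = 0.368) and Erbb2 (-0.06, 0.798) did not pass. The Erbb3 call ended without PBS replicate 2 (0.0951), NRG1 replicate 1 (0.0809) or NRG1 replicate 2 (0.0845). Myc fell by 0.55 on the log2 scale (adjusted p = 0.0085). Ccnd1, a cyclin of G1, fell by 0.55 (adjusted p = 0.0103), a call that ended without NRG1 replicate 1 (0.0639).

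The G2/M list rose for 26 of 28 genes in Lgr5high cells (27 adjusted over the list alone; median 0.80, camera adjusted p = 1.51e-48, and 0.165 with an estimated correlation). The S phase list fell for 18 of 29 genes (22 adjusted over the list alone; median -0.61, camera adjusted p = 4.25e-24, and 0.165 with an estimated correlation). As a share of the counts outside mitochondrial ribosomal RNA, G2/M genes took 1.13 ± 0.129% against 0.679 ± 0.0415% and S phase genes 0.185 ± 0.0138% against 0.282 ± 0.0217% (n = 3, exact permutation p = 0.1 for each, the smallest possible). Paneth markers fell for 7 of 19 genes (9 adjusted over the list alone; median -0.76, camera adjusted p = 1.6e-08, and 0.537 with an estimated correlation), with the defensin gene Gm15284 at 196 ± 37.4 against 537 ± 145 CPM. Ribosome biogenesis genes fell for 3 of 26, among them Gnl3 at -0.61 (9 lower and 1 higher adjusted over the list alone; median -0.27, 3.8e-05, and 0.537 with an estimated correlation). Antigen presentation genes fell for 5 of 26 (8 lower and 1 higher adjusted over the list alone; median -0.41, 1.72e-06, and 0.537), among them Psmb9, an immunoproteasome subunit, at -0.99. Fatty acid oxidation genes fell for 3 of 25 (3 adjusted over the list alone; median -0.24, 0.00314, and 0.687), among them Ppara at -0.785.

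With the replicate number as a block, Wnt targets, enterocyte and enteroendocrine markers were also called in Lgr5high cells. In the main test camera called none of the other lists there. The adjusted p was 0.0532 for Wnt targets and for glycolysis, 0.0537 for mitochondrially encoded genes and 0.0548 for enteroendocrine markers. It was 0.183 for enterocyte markers, 0.284 for the unfolded protein response, 0.415 for antimicrobial genes, and 0.443 for immediate-early genes and p53 targets. It was 0.615 for the Notch pathway, 0.618 for regenerative genes and cholesterol biosynthesis, 0.626 for ErbB receptors and ligands, 0.866 for ERK feedback genes, 0.915 for tuft markers and 0.998 for goblet markers. Of 17 measured ERK feedback genes 1 rose and 4 fell. Mesenchymal, neural and erythroid markers had 4, 4 and 1 genes past the filter over all libraries, too few for a test.

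**Figure D3:**
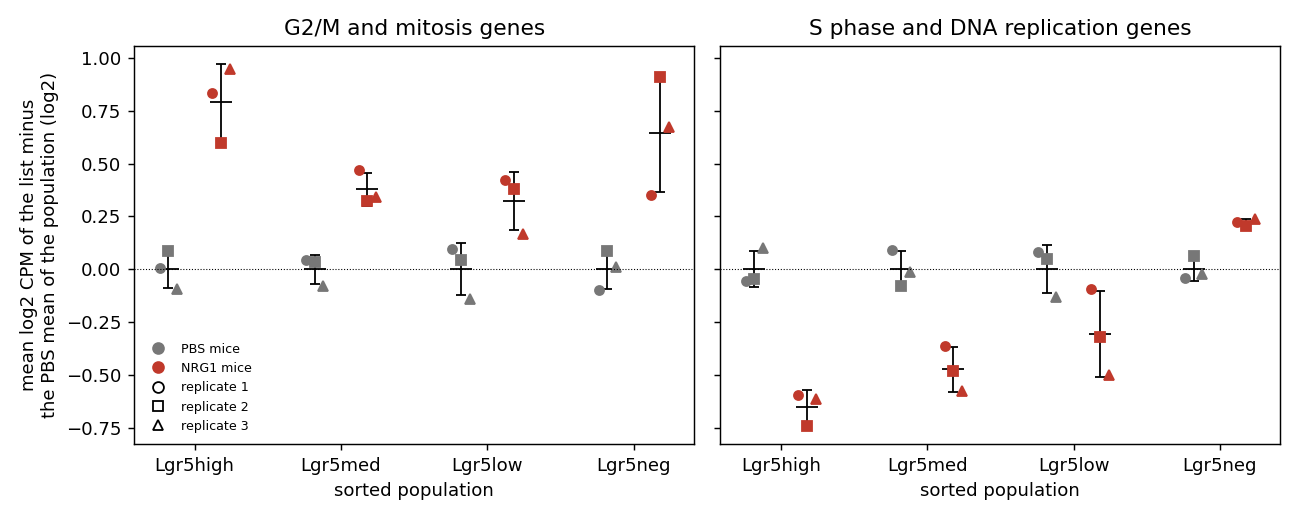
Mean log2 CPM of the G2/M and the S phase list per library, relative to the PBS mean of the population; points are libraries (shape gives the replicate, grey PBS, red NRG1) and black bars the mean ± SD of 3 libraries. In Lgr5high cells the G2/M list rises (median log2 change 0.80) while the S phase list falls (-0.61).

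In Lgr5med cells, the immediate progenitors, 1279 of 13394 genes changed under NRG1 (504 higher and 775 lower), 60 of the rises and 172 of the falls by more than 2-fold. With the replicate number as a block 2333 genes changed. Car4, a carbonic anhydrase, was 5.48-fold lower at 3.67 ± 1.14 against 20.1 ± 3.80 CPM (NRG1 against PBS, n = 3; log2 change -2.45, SE 0.237, adjusted p = 7.05e-05; chromosome 11, 84957786 to 84966044). Fabp1, an enterocyte fatty acid binding protein, fell from 162 ± 34.8 to 55.0 ± 6.93 CPM (-1.55, SE 0.156, adjusted p = 8.93e-05; chromosome 6, 71199827 to 71205023). Ung fell from 86.1 ± 14.6 to 19.6 ± 4.33 CPM (-2.13, SE 0.174, adjusted p = 5.64e-05), and E2f1 fell by 2.00. Trp53inp1, a p53-induced gene, rose from 9.58 ± 1.44 to 31.0 ± 4.13 CPM (1.70, SE 0.167, adjusted p = 7.05e-05). Ldha, a glycolytic enzyme, fell from 602 ± 29.6 to 334 ± 40.1 CPM. Erbb3 rose from 158 ± 12.6 to 249 ± 6.86 CPM (0.65, SE 0.118, adjusted p = 0.00456), and Spry2, an inhibitor of receptor tyrosine kinase signalling, fell by 0.92. Without PBS replicate 2, 121 genes were higher and 323 lower, and the count of genes was 422 without PBS replicate 3 and 572 without NRG1 replicate 2.

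Stem cell markers were higher in NRG1-treated Lgr5med cells for 3 of 28 genes (3 adjusted over the list alone; median 0.36, camera adjusted p = 0.000101, and 0.804 with an estimated correlation). The libraries overlapped: relative to the PBS mean, the list score of PBS replicate 1 was 0.517, above NRG1 replicates 2 (0.451) and 3 (0.224). Lgr5 (0.93, adjusted p = 0.398) and Olfm4 (0.85, adjusted p = 0.101) did not pass by themselves. With the replicate block their adjusted p was 2.05e-05 and 0.00184, within ranges over the alternatives run for single genes of 2.05e-05 to 0.639 for Lgr5 and 0.00121 to 0.244 for Olfm4. Enterocyte markers fell for 7 of 30 genes (8 adjusted over the list alone; median -0.48, camera adjusted p = 1.59e-05, and 0.584 with an estimated correlation), and antimicrobial genes for 3 of 15 (5 adjusted over the list alone; median -0.39, 0.00356, and 0.584). G2/M genes rose for 12 of 28 (21 adjusted over the list alone; median 0.45, 1.96e-10, and 0.421), among them Cenpa at 0.92. S phase genes fell for 9 of 29 (18 lower and 1 higher adjusted over the list alone; median -0.42, 6.3e-09, and 0.421), among them Uhrf1 at -0.99. Ribosome biogenesis genes fell for 6 of 26 (6 adjusted over the list alone; median -0.23, 0.00471, and 0.612). The p53 targets rose for 3 of 22 (4 adjusted over the list alone; median 0.27, 0.00373, and 0.421), and mitochondrially encoded genes for 3 of 8 (5 adjusted over the list alone; median 0.46, 1.14e-05, and 0.531).

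Other lists in Lgr5med cells were called with all libraries but not with each library left out. Enteroendocrine markers (median -0.54, 1 of 22 lower, 1 adjusted over the list alone; adjusted p = 0.027, and 0.925 with an estimated correlation) lost the call without PBS replicate 2 (0.197) or NRG1 replicate 1 (0.286). Glycolysis (median -0.15, 5 of 21 lower, 6 adjusted over the list alone; 0.00804, and 0.531) lost it without PBS replicate 3 (0.0551) or NRG1 replicate 3 (0.0625). The unfolded protein response (median -0.26, 3 of 20 lower, 4 adjusted over the list alone; 0.0075, and 0.818) lost it without PBS replicate 3 (0.126) or NRG1 replicate 1 (0.109). Antigen presentation (median -0.37, 4 of 26 lower, 4 adjusted over the list alone; 0.0075, and 0.612) lost it without PBS replicate 2 (0.0762) or NRG1 replicate 3 (0.0529). Fatty acid oxidation (median -0.20, 3 of 25 lower, 3 adjusted over the list alone; 0.0264, and 0.826) lost it without PBS replicate 1 (0.150), PBS replicate 3 (0.0595), NRG1 replicate 2 (0.0690) or NRG1 replicate 3 (0.224). Goblet markers had a median of -0.44 and an adjusted p of 0.123, which was 8.29e-05 with the replicate block, within a range over the alternatives run for it of 8.95e-07 to 0.925.

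In Lgr5low cells, the subsequent progenitors, 59 of 13326 genes changed under NRG1 (19 higher and 40 lower), and 573 with the replicate number as a block. Trmt61a, a tRNA methyltransferase subunit, fell by 1.58 on the log2 scale (SE 0.163, adjusted p = 0.00271) and passed with each library left out. Olfm4 rose from 253 ± 21.8 to 563 ± 174 CPM (NRG1 against PBS, n = 3; 1.16, SE 0.196, adjusted p = 0.0369; chromosome 14, 79984081 to 80023139). Its call ended without PBS replicate 1 (0.110), PBS replicate 2 (0.119), PBS replicate 3 (0.0669) or NRG1 replicate 2 (0.276). Prelp, an extracellular matrix proteoglycan, rose from 41.6 ± 2.95 to 101 ± 17.3 CPM (1.28, SE 0.150, adjusted p = 0.00645), a call that ended without PBS replicate 2 (0.0597) or NRG1 replicate 2 (0.0679). Ung fell by 1.34 (adjusted p = 0.0154), a call that ended without PBS replicate 1 (0.0694), PBS replicate 2 (0.0777) or NRG1 replicate 2 (0.175). Erbb3 was at 255 ± 7.69 against 175 ± 19.8 CPM and did not pass (0.54, adjusted p = 0.111). With the replicate block its adjusted p was 0.0121, within a range over the alternatives run for it of 0.0121 to 0.426. The count of genes was 3 without PBS replicate 1, 3 without PBS replicate 2, 33 without PBS replicate 3 and 1 without NRG1 replicate 2, and 129 with all 24 libraries in 1 model.

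Stem cell markers rose in Lgr5low cells for 4 of 28 genes (11 adjusted over the list alone; median 0.47, camera adjusted p = 6.48e-13, and 0.387 with an estimated correlation). Enterocyte markers had a median of -0.56 with none of 30 passing over all genes and 6 lower adjusted over the list alone (1.46e-10, and 0.66). G2/M genes had a median of 0.34 with 1 of 28 passing, 7 adjusted over the list alone (3.1e-10, and 0.622). S phase genes had a median of -0.16 with none of 29 passing, 2 adjusted over the list alone (0.000445, and 0.697), and antimicrobial genes a median of -0.38 with none of 14 passing, 5 adjusted over the list alone (0.0012, and 0.387). Fatty acid oxidation (median -0.28, 0 of 26; 0.00101, and 0.859) lost its call without NRG1 replicate 2 (0.0725). Glycolysis (median -0.18, 0 of 22; 0.0227, and 0.387) lost it without PBS replicate 3 (0.0986) or NRG1 replicate 2 (0.0578). Antigen presentation (median -0.21, 0 of 27; 0.00449, and 0.66) lost it without PBS replicate 2 (0.0534) or NRG1 replicate 2 (0.192).

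In Lgr5neg cells, the differentiated cells, 39 of 11908 genes changed under NRG1 (18 higher and 21 lower), and 839 with the replicate number as a block. Axin2 was 2.64-fold lower at 9.90 ± 1.00 against 26.1 ± 1.73 CPM (n = 3; log2 change -1.40, SE 0.164, adjusted p = 0.00988; chromosome 11, 108920349 to 108950783). Its call ended without PBS replicate 1 (0.0820) or PBS replicate 3 (0.0595). Saa1, an acute-phase protein, fell from 5.97 ± 0.572 to 0.772 ± 0.452 CPM (-2.93, SE 0.391, adjusted p = 0.0149), a call that ended without PBS replicate 1 (0.103) or PBS replicate 3 (0.103). Gpx1, a glutathione peroxidase, rose from 122 ± 8.65 to 282 ± 58.8 CPM (1.22), a call that ended without PBS replicate 1 (0.1095), PBS replicate 2 (0.107) or PBS replicate 3 (0.199). Erbb3 was at 360 ± 18.4 against 232 ± 26.5 CPM and did not pass (0.63, adjusted p = 0.157). With the replicate block its adjusted p was 0.000314, within a range over the alternatives run for it of 0.000314 to 0.402. Muc2 (-1.06, adjusted p = 0.399) and Chgb, an enteroendocrine granin (-1.22, adjusted p = 0.507), did not pass. With the replicate block the adjusted p of Chgb was 1.61e-05, within a range over the alternatives run for it of 1.61e-05 to 0.740. The count of genes was 0 without PBS replicate 1, 4 without PBS replicate 2, 0 without PBS replicate 3, 90 without NRG1 replicate 1, 12 without NRG1 replicate 2 and 15 without NRG1 replicate 3, and 306 with all 24 libraries in 1 model. Beside the counts of 0 by edgeR, 1257 genes had an unadjusted p under 0.05 with all libraries, and DESeq2 called 197.

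Goblet markers were lower in NRG1-treated Lgr5neg cells at a median of -0.76, with none of 17 passing over all genes and 7 adjusted over the list alone (camera adjusted p = 4.03e-11, and 0.238 with an estimated correlation). Enteroendocrine markers had a median of -1.46 with none of 11 passing, 6 adjusted over the list alone (4.02e-08, and 0.238). G2/M genes had a median of 0.62 with none of 28 passing, 3 adjusted over the list alone (1.13e-10, and 0.238). ERK feedback genes had a median of -0.51 with none of 16 passing, 2 adjusted over the list alone (0.000586, and 0.238), and immediate-early genes a median of -0.46 with none of 19 passing, 4 adjusted over the list alone (0.000687, and 0.238). These 5 lists kept their calls with each library left out.

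The remaining lists called in Lgr5neg cells each lost the call without 1 or more libraries. Enterocyte markers (median -0.24, 0 of 30, 5 adjusted over the list alone; 0.000586, and 0.556 with an estimated correlation) lost it without PBS replicate 1 (0.117) or NRG1 replicate 2 (0.152). S phase genes (median 0.26, 0 of 27; 0.0497, and 0.238) lost it without PBS replicate 1 (0.114), PBS replicate 3 (0.0603), NRG1 replicate 1 (0.214) or NRG1 replicate 3 (0.0572), and with the replicate block (0.0835, within a range over the alternatives run for it of 0.0311 to 0.238). Wnt targets (median -0.24, 1 of 15 lower, 2 adjusted over the list alone; 0.015, and 0.274) lost it without PBS replicate 3 (0.0603) or NRG1 replicate 1 (0.175). Regenerative genes (median -0.33, 0 of 11, 3 adjusted over the list alone; 0.015, and 0.394) lost it without PBS replicate 1 (0.114) or NRG1 replicate 1 (0.0594). Paneth markers (median -0.47, 0 of 18; 0.015, and 0.632) lost it without PBS replicate 2 (0.280), PBS replicate 3 (0.140) or NRG1 replicate 1 (0.828). Antigen presentation (median -0.31, 0 of 30; 0.00155, and 0.556) lost it without NRG1 replicate 2 (0.0521) or NRG1 replicate 3 (0.0745). Antimicrobial genes (median -0.34, 1 of 15 lower, 1 adjusted over the list alone; 0.00317, and 0.238) lost it without NRG1 replicate 1 (0.0594). Mitochondrially encoded genes (median 0.31, 0 of 8; 0.00386, and 0.556) lost it without PBS replicate 2 (0.0870) or NRG1 replicate 3 (0.140). The unfolded protein response, with a median of -0.16 and an adjusted p of 0.0887, was called with the replicate block (0.0495, within a range over the alternatives run for it of 0.00104 to 0.614). Immune markers were not called (median 0.59 over 15 genes, adjusted p = 0.459).

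**Figure D4:**
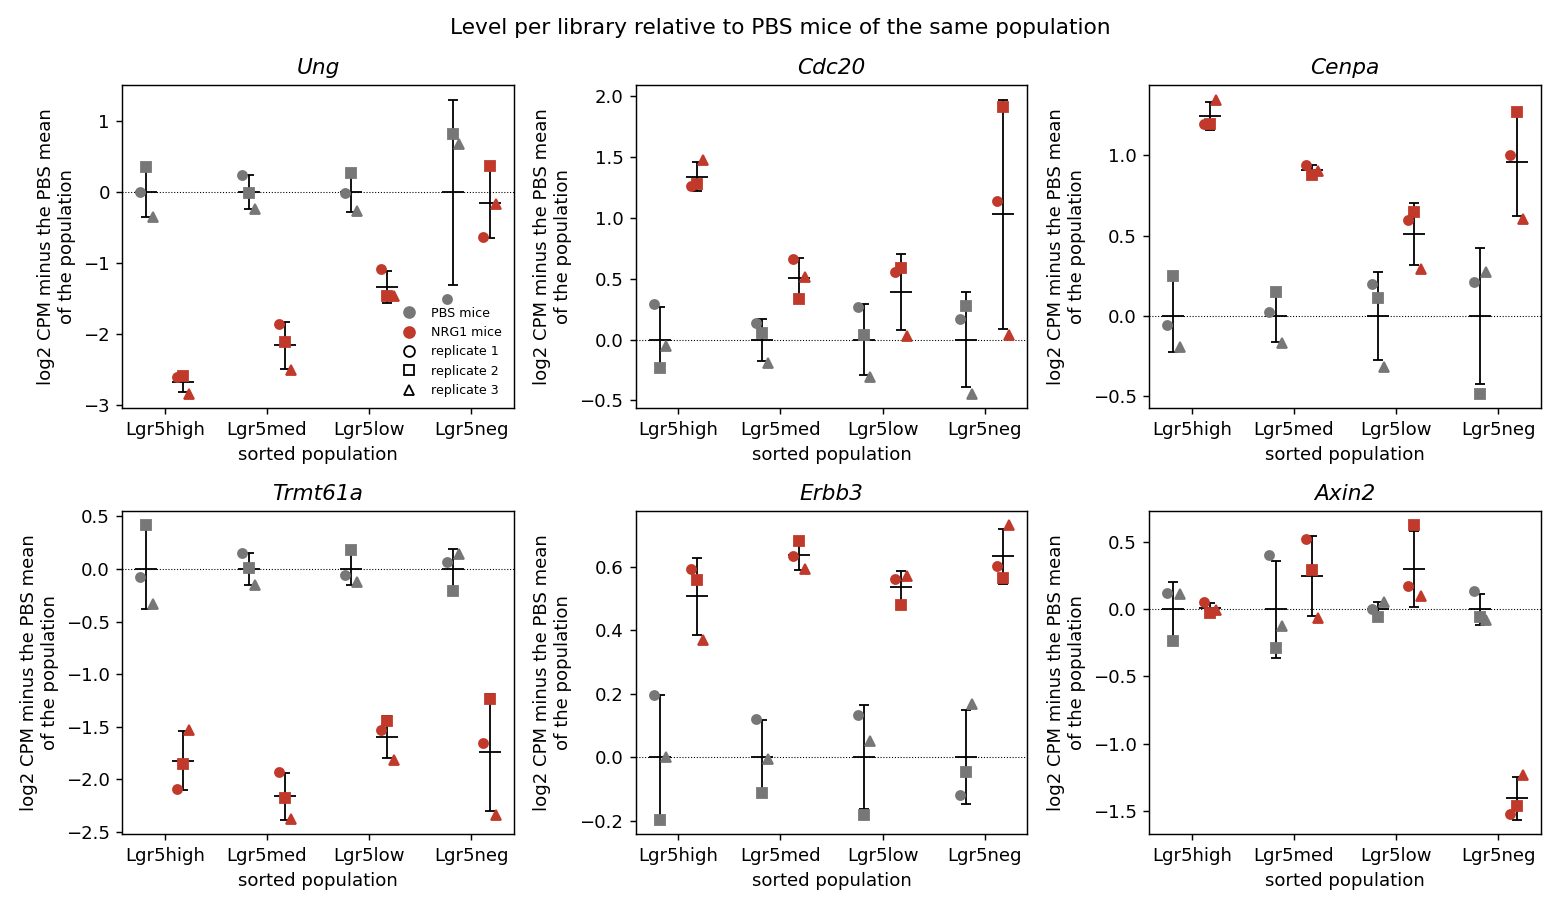
Log2 CPM (over all 24 libraries) of 6 genes per library, relative to the PBS mean of the population; points are libraries (shape gives the replicate, grey PBS, red NRG1) and black bars the mean ± SD of 3 libraries. In every population Trmt61a is lower and Erbb3 higher in all NRG1 than in all PBS libraries, Ung falls most in Lgr5high cells (log2 change -2.69), Cdc20 and Cenpa rise in Lgr5high cells, and Axin2 falls in Lgr5neg cells (log2 change -1.40).

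The third question was whether the NRG1 response of Lgr5high stem cells differed from that of the other populations. By edgeR's interaction test over 15045 genes, 0 genes differed from the response of Lgr5med cells (576 at an unadjusted p under 0.05, 0 by DESeq2) and 0 from that of Lgr5low cells (676, and 0 by DESeq2). Without the filter on low counts some genes passed in both of these interactions. From the response of Lgr5neg cells 8 genes differed (2 higher and 6 lower, 1303 at an unadjusted p under 0.05, 47 by DESeq2), 65 with the mouse as a replicate block and 0 with counts thinned to the smallest library. Clic4, an intracellular chloride channel protein, had the smallest adjusted p (log2 difference 1.46, SE 0.193, adjusted p = 0.00048). It had 2.84 ± 0.417 against 6.27 ± 0.490 CPM in Lgr5neg cells (NRG1 against PBS) and 63.8 ± 1.87 against 51.0 ± 5.85 CPM in Lgr5high cells, and it passed with each library left out but, like every gene, not with the thinned counts. The count was 4 without Lgr5high PBS replicate 1, 4 without Lgr5high PBS replicate 2, 2 without Lgr5high PBS replicate 3, 1 without Lgr5high NRG1 replicate 1, 3 without Lgr5high NRG1 replicate 2, 3 without Lgr5neg PBS replicate 1, 4 without Lgr5neg PBS replicate 2, 5 without Lgr5neg NRG1 replicate 1, 2 without Lgr5neg NRG1 replicate 2 and 18 without Lgr5neg NRG1 replicate 3.

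The G2/M list rose more in Lgr5high than in Lgr5med cells (median difference 0.39, camera adjusted p = 2.43e-14, and 0.276 with an estimated correlation; no gene passed over all genes) and more than in Lgr5low cells (0.45, 2.02e-18, and 0.0606; 9 of 28 genes adjusted over the list alone). The change of the stem cell list, which was not called in Lgr5high cells, lay lower there than in Lgr5med cells (-0.46, 4.76e-10, and 0.562) and lower than in Lgr5low cells (-0.62, 1.16e-11, and 0.280; 4 of 28 genes adjusted over the list alone). Of the lists called against Lgr5neg cells, the S phase list moved most (-0.88, 1.15e-22, and 0.00176). Of its genes 2 passed over all genes and 17 adjusted over the list alone. Its median in PBS Lgr5neg cells lay at -3.82 (log2) relative to Lgr5high cells, so the Lgr5neg part of this difference rests on low levels. The other part is the fall of the list in Lgr5high cells. The G2/M list was not called against Lgr5neg cells.

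The populations shared many of their changes. Lgr5high and Lgr5med cells had 167 genes higher in both (16.4 expected from independent lists) and 266 lower in both (32.3 expected), and none changed in opposite directions. Across 12890 genes their log2 changes correlated at r = 0.56, against 0.085 to 0.37 for the other splits of the same mice. The other pairs correlated at 0.37 (Lgr5high and Lgr5neg) to 0.60 (Lgr5med and Lgr5low). Each lay above the other splits of its pair, and none had genes changed in opposite directions. Genes are not independent replicates, and the same 6 mice gave all populations.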

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

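The tests of splits of the mice, of GC content, of another sorted population, of depth, of library preparation, of the sequence match as reported here and of the rise of remaining genes were chosen after the results were seen; the ratio of implied shares and the slope were chosen before. Each value here is a difference between the NRG1 effect in Lgr5high cells and that in another population, by the interaction test of edgeR for genes or camera for lists. With an estimated correlation all list calls were lost except those of S phase and ERK feedback genes against Lgr5neg cells. Most of the values thus do not establish a response that differs between sorted populations. For the genes counted in these comparisons the splits of the mice number 10, too few for a share under 0.05. The 3 counts were 0, 0 and 8 genes for Lgr5med, Lgr5low and Lgr5neg cells, the highest counts of the other splits were 0, 0 and 2, and as many genes were reached by 10, 10 and 1 of the splits.

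The G2/M list rose more in Lgr5high cells than in Lgr5med (0.394) and Lgr5low cells (0.450) but was not called against Lgr5neg cells. The S phase list fell more in Lgr5high than in Lgr5med (-0.142) and Lgr5low cells (-0.325) and differed by -0.884 from Lgr5neg cells, where its median was 0.26. With an estimated correlation the adjusted p was 0.276 and 0.0606 for G2/M, and 0.625, 0.0606 and 0.00176 for S phase in the same order, so of these only S phase against Lgr5neg cells was called. The Lgr5neg part of that difference rests on low levels, as the S phase median of PBS Lgr5neg cells lay at -3.82 (log2) relative to Lgr5high cells. The other part is the fall of the list in Lgr5high cells. The medians of both lists lay 1.42 apart (log2) in Lgr5high cells, and the tables argue against GC content and gene length as the cause, since the gap was 1.44 with that trend removed, and against depth, since it was 1.43 with counts thinned to 1 depth. Cells of another of the sorted populations in the gate cannot explain the G2/M rise, since the G2/M median of PBS cells was highest in Lgr5high cells and the next population lay at -0.109. The S phase median was lower in PBS Lgr5med (-0.247) and Lgr5low cells (-0.723) too, so such cells are not excluded for the S phase fall. A larger share of stem cells in G2 and mitosis was not tested, and a difference in library preparation stays open too, since mt-Rnr1 per 100 mt-Rnr2 was 51.6, 39.9 and 38.6 in the NRG1 and 18.1, 24.2 and 42.9 in the PBS libraries of Lgr5high cells.

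Of these lists, G2/M against both progenitor populations and S phase against Lgr5low and Lgr5neg cells kept their calls with each library left out. S phase against Lgr5med cells lost its call without Lgr5high PBS replicate 3 (adjusted p = 0.0672), Lgr5high NRG1 replicate 2 (0.108), Lgr5med PBS replicate 2 (0.0573) or Lgr5med NRG1 replicate 1 (0.0973), within a range of 0.000444 to 0.766 over the alternatives run for it.

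The change of stem cell markers lay lower in Lgr5high cells, where they were not called, than in Lgr5med (-0.464) and Lgr5low cells (-0.615), calls that held with each library left out but were lost with an estimated correlation (adjusted p = 0.562 and 0.280). In Lgr5med cells their rise went with a fall of enterocyte genes. The enterocyte median was -0.388 with the GC and length trend removed, which argues against that trend as the cause of the fall. That value does not speak to the rise of stem markers. Fewer Lgr5neg cells in the Lgr5med gate cannot explain the rise of stem markers. The loss of Lgr5neg RNA that other genes imply would raise all remaining genes by 0.0217 (log2). That value covers Lgr5neg cells only, and a changed share of Lgr5high or Lgr5low cells in the gate was not tested. For the enterocyte fall, fewer Lgr5neg cells and a change within the cells cannot be told apart. The implied loss of Lgr5neg RNA had a ratio of 1.81 between the 216 other genes and 27 enterocyte markers. Its 95% interval of 1.00 to 2.68 held the bound of 2. That interval resamples genes and leaves out the spread between mice. Lgr5med cells may instead lie nearer to the stem cell profile under NRG1. The slope of the NRG1 change on the PBS difference of Lgr5high and Lgr5low cells was 0.156. Another split of the mice gave an absolute slope of 0.219, and 10 splits are too few to decide. The bound set beforehand counted that larger slope against the idea. That bound was wrong, because so few splits cannot tell an effect from the spread between mice.

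Mitochondrially encoded genes rose less in Lgr5high than in Lgr5med cells (-0.347), a call that ended without Lgr5high PBS replicate 3 (adjusted p = 0.0594) or Lgr5med PBS replicate 2 (0.116), with an estimated correlation (0.859) and with the GC and length trend removed (-0.0757, 0.609), within 0.000296 to 0.875 over the alternatives run for it. The members did not move together: in Lgr5med cells mt-Co1 rose by 1.40 (adjusted p = 0.000597) while mt-Nd1 changed by -0.01 (0.984), and mt-Rnr1 rose by 1.11 (0.00471) while mt-Rnr2 changed by -0.07 (0.871). GC content thus stays open for the list difference but cannot part its members, as mt-Co1 and mt-Nd1 have 39.9% and 37.6% GC and moved 1.40 apart, and reads shared with mt-Rnr1 do not explain the values of mt-Co1 and Lars2 (a nuclear gene outside the list, Lgr5high 1.07, adjusted p = 0.271), whose annotated transcripts matched it over 0 bases, while Gm23935, at 57 bases, is too short for this search and stays open. A difference in library preparation that the labels do not record cannot be told apart from NRG1: counts of mt-Rnr1 per 100 mt-Rnr2 lay above those of PBS in all NRG1 libraries of their population, except that 1 PBS library (Lgr5high replicate 3, 42.9) lay among the NRG1 values of 38.6 to 51.6.

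Further list differences from Lgr5med cells were -0.288 for Wnt targets and -0.897 for Paneth markers, both lost with an estimated correlation (adjusted p = 0.871 for each). The Paneth call ended without Lgr5med PBS replicate 1 (0.132) or Lgr5med NRG1 replicate 2 (0.0796), with 3.33e-07 to 0.875 over the alternatives run for it. The Wnt call ended without Lgr5high PBS replicates 1 (0.489) or 3 (0.122), Lgr5high NRG1 replicates 2 (0.120) or 3 (0.0513), Lgr5med PBS replicates 2 (0.543) or 3 (0.121), or Lgr5med NRG1 replicates 1 (0.351) or 2 (0.0796), with 4.06e-05 to 0.875 over the alternatives run for it.

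Further list differences from Lgr5low cells were -0.250 for ribosome biogenesis, which held with each library left out but not with an estimated correlation (adjusted p = 0.679), -0.354 for Wnt targets, 0.257 for enterocyte markers, -0.869 for Paneth markers and -0.899 for tuft markers, the last 4 lost with an estimated correlation too (0.731, 0.866, 0.866 and 0.731). The Wnt call ended without Lgr5high PBS replicates 1 (0.271) or 3 (0.0687), Lgr5high NRG1 replicate 2 (0.0750) or Lgr5low NRG1 replicate 2 (0.251), with 9.09e-05 to 0.856 over the alternatives run for it. The Paneth call ended without Lgr5low PBS replicate 1 (0.616) or Lgr5low NRG1 replicates 2 (0.251) or 3 (0.289), with 1.66e-10 to 0.866 over the alternatives run for it. The tuft call ended without Lgr5high PBS replicate 2 (0.381), Lgr5low PBS replicates 1 (0.129) or 3 (0.0664), or Lgr5low NRG1 replicates 2 (0.251) or 3 (0.104), with 0.000156 to 0.856 over the alternatives run for it. The enterocyte call ended with the mouse as a block (0.0790) and without Lgr5high PBS replicates 1 (0.228) or 3 (0.381), Lgr5high NRG1 replicate 2 (0.337, where the difference turned to -0.264), Lgr5low PBS replicates 1 (0.286) or 3 (0.255), or Lgr5low NRG1 replicates 1 (0.066) or 2 (0.738), with 3.44e-05 to 0.866 over the alternatives run for it.

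Further list differences from Lgr5neg cells were -0.385 for ribosome biogenesis and 0.594 for ERK feedback genes, both held with each library left out (with an estimated correlation 0.437, which ends the first call, and 0.0301), then 0.460 for goblet markers, 0.678 for regenerative genes, 0.51 for the Notch pathway and -0.228 for fatty acid oxidation, these 4 lost with an estimated correlation (0.936, 0.305, 0.272 and 0.979). The goblet call ended without Lgr5high PBS replicate 1 (0.173), with 4.43e-11 to 0.936 over the alternatives run for it. The regenerative call ended without Lgr5high NRG1 replicate 2 (0.0603) or Lgr5neg PBS replicate 1 (0.138), with 0.00115 to 0.305 over the alternatives run for it. The fatty acid oxidation call ended without Lgr5high PBS replicate 1 (0.109), Lgr5high NRG1 replicates 2 (0.0533) or 3 (0.143), Lgr5neg PBS replicate 2 (0.280) or Lgr5neg NRG1 replicate 1 (0.422), with 0.00148 to 0.979 over the alternatives run for it. The Notch call ended without Lgr5high PBS replicates 1 (0.122) or 3 (0.0603), Lgr5high NRG1 replicates 1 (0.0735) or 3 (0.143), Lgr5neg PBS replicates 1 (0.243) or 2 (0.204), or Lgr5neg NRG1 replicates 1 (0.531) or 3 (0.0583), with 0.00478 to 0.531 over the alternatives run for it.

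Single genes whose NRG1 effect differed from that in Lgr5neg cells were Tcf19 at -3.05, Cd320 at -2.075, Cdc6 at -1.87, Mcm6 at -1.315, Rps28 at -1.31, Axin2 at 1.405 and Clic4 at 1.46. Fam101b, at -1.19, falls outside the rule for named genes and was chosen after its value was seen. In Lgr5high cells Cdc6 fell by 1.43 (adjusted p = 0.000332) and Tcf19 by 1.05 (0.00256), while in Lgr5neg cells Cdc6 changed by 0.46 (0.788) and Tcf19 had too few counts for a test. Cd320 changed by -0.04 in Lgr5high cells (0.917) and by 2.02 in Lgr5neg cells (0.146). Levels in Lgr5neg cells (NRG1 against PBS) were low for Cdc6 (1.38 against 0.995 CPM), Mcm6 (4.00 against 3.54) and Cd320 (1.47 against 0.355). They were higher for Rps28 (25.9 against 12.75), Axin2 (9.90 against 26.1) and Fam101b (32.4 against 26.4). The Axin2 call ended without Lgr5high PBS replicate 2 (0.0629), Lgr5high NRG1 replicate 1 (0.0669), Lgr5neg PBS replicate 1 (0.0559) or Lgr5neg NRG1 replicate 2 (0.0516), with 0.000353 to 0.0669 over the alternatives run for it. The Tcf19 call ended without Lgr5high PBS replicates 1 (0.0781), 2 (0.0679) or 3 (0.0603), Lgr5high NRG1 replicates 1 (0.0773), 2 (0.088) or 3 (0.0506), Lgr5neg PBS replicates 1 (0.121) or 2 (0.11), or Lgr5neg NRG1 replicates 1 (0.135) or 2 (0.0685), with 0.0234 to 0.135 over the alternatives run for it. The Cd320 call ended without Lgr5high PBS replicates 1 (0.0625) or 3 (0.0692), Lgr5high NRG1 replicate 1 (0.0805), Lgr5neg PBS replicates 1 (0.0615) or 2 (0.0964), or Lgr5neg NRG1 replicates 1 (0.0546) or 2 (0.0516), with 0.00318 to 0.0964 over the alternatives run for it. The Cdc6 call ended without Lgr5high PBS replicates 1 (0.0625), 2 (0.0759) or 3 (0.0603), Lgr5high NRG1 replicates 1 (0.104) or 2 (0.0635), Lgr5neg PBS replicates 2 (0.0964) or 3 (0.0631), or Lgr5neg NRG1 replicate 1 (0.13), with 0.00082 to 0.13 over the alternatives run for it. The Mcm6 call ended without Lgr5high PBS replicates 2 (0.0679) or 3 (0.104), Lgr5high NRG1 replicates 1 (0.0669), 2 (0.111) or 3 (0.116), Lgr5neg PBS replicates 2 (0.0964) or 3 (0.0755), or Lgr5neg NRG1 replicates 1 (0.106) or 2 (0.107), with 0.00196 to 0.116 over the alternatives run for it. The Rps28 call ended without Lgr5high PBS replicate 3 (0.0886), Lgr5high NRG1 replicates 1 (0.104) or 2 (0.088), Lgr5neg PBS replicates 1 (0.0616), 2 (0.0668) or 3 (0.0595), or Lgr5neg NRG1 replicates 1 (0.0649) or 2 (0.0587), with 0.00152 to 0.104 over the alternatives run for it.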

How the results depend on the processing

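Tests of thinned counts, of counts without mitochondrial ribosomal RNA of the GC and length correction and of splits of the libraries were chosen after the data were seen. DESeq2 size factors, the filter of 5 CPM in 3 libraries, the GC and length correction and the removal of mitochondrial ribosomal RNA moved none of the 11 counts of changed genes by more than 1.5 times. The cause of the other shifts was not tested. At an adjusted p under 0.10, which is a looser threshold by construction, the counts were 1643 in Lgr5high, 2107 in Lgr5med, 151 in Lgr5low and 85 in Lgr5neg cells under NRG1, 1623 for Lgr5med against Lgr5low, and 24 for the interaction with Lgr5neg. With all 24 libraries in 1 model they were 480 in Lgr5high, 129 in Lgr5low and 306 in Lgr5neg cells. The replicate block gave 2333 in Lgr5med, 573 in Lgr5low and 839 in Lgr5neg cells, and with the mouse as the block 1 for the interaction with Lgr5low and 65 for that with Lgr5neg. The block with the GC and length correction gave 1969, 581 and 832 for the same populations, 1659 for Lgr5med against Lgr5low, and 1, 3 and 45 for the interactions with Lgr5med, Lgr5low and Lgr5neg. DESeq2's Wald test gave 306 in Lgr5low and 197 in Lgr5neg cells and 47 for the interaction with Lgr5neg. Without a filter on low counts there were 497 in Lgr5low and 272 in Lgr5neg cells, and 17, 35 and 150 for the interactions. Age as a block gave 136 in Lgr5low cells. Limma voom gave 208 in Lgr5low and 180 in Lgr5neg cells. Thinned counts gave 0 for the interaction with Lgr5neg, where edgeR on all counts had 1303 genes at an unadjusted p under 0.05 and DESeq2 called 47. With the block, voom or no filter, the share of rises among the Lgr5neg calls was 35.4% to 36.1% against 46.2%.

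With 1 library left out, the counts ranged from 491 to 1186 in Lgr5high, 422 to 1118 in Lgr5med, 1 to 72 in Lgr5low and 0 to 90 in Lgr5neg cells, from 634 to 1425 for Lgr5high against Lgr5med, 464 to 1004 for Lgr5med against Lgr5low, 7183 to 7725 for Lgr5low against Lgr5neg, 9079 to 9338 for Lgr5high against Lgr5neg, and 1 to 18 for the interaction with Lgr5neg. List directions reversed in 4 cases. The immune list in Lgr5neg cells under NRG1 was -0.646 without Lgr5neg NRG1 replicate 2, in a range up to 1.06. The fatty acid oxidation list there was -0.178 without Lgr5neg NRG1 replicate 1, in a range up to 0.0725. The glycolysis list of Lgr5high against Lgr5med was 0.0246 without Lgr5high PBS replicate 1, in a range down to -0.176. The enterocyte interaction with Lgr5low was -0.264 without Lgr5high NRG1 replicate 2, in a range up to 0.611. Called lists kept their calls in every setting for 6 of 6 in Lgr5high, 8 of 13 in Lgr5med, 5 of 8 in Lgr5low and 5 of 13 in Lgr5neg cells, leaving aside the estimated correlation and fry. The estimated correlation ended all of these calls. No named gene reversed. Named genes passed with each library left out for 27 of 42 in Lgr5high, 26 of 42 in Lgr5med, 1 of 18 in Lgr5low and 0 of 17 in Lgr5neg cells.

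In Lgr5high cells the replicate pairs correlated at 0.084 to 0.278, and 5 of 6 libraries lay closest to their own number. By the bound of 0.1 the numbers were not taken as pairs there, although they mark the same mice as in the other populations. The block gave 1229 genes and added calls for Wnt targets, enterocyte and enteroendocrine markers. Over all comparisons the block added a call for 29 named genes, those printed with the results among them, and ended 1, and besides these and the lists printed with the results it changed no other call. The splits of 3 against 3 libraries number 10, too few for a share under 0.05, and 1 of them, the real one, reached each count under NRG1. The real counts were 976, 1279, 59 and 39 from Lgr5high to Lgr5neg, against at most 0, 0, 0 and 1 in the other splits. In the PBS comparisons they were 1302, 1078, 7931 and 9576 against at most 0, 1, 0 and 0. The smallest library, Lgr5low NRG1 replicate 1, had 6192378 counts outside mitochondrial ribosomal RNA. Thinned to the smallest library of each comparison, the counts gave 997, 1246, 67 and 40 genes under NRG1, so unequal totals within a comparison did not set these 4 numbers. Depth still differed between the comparisons, and the totals include mitochondrial ribosomal RNA. The thinning thus cannot tell whether depth adds to the differences between the 4 numbers.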

Other observations

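The tests of the shifts along the differentiation axis and of genes that moved in every population were chosen before their results were seen, though the GC content of those genes was already known; the immune and goblet shares were picked out after their tests were seen. Immune markers sat almost only in Lgr5neg libraries, where Gzmb and Ccl5, a chemokine of cytotoxic T cells, stood at 33.0 ± 12.2 and 18.7 ± 10.2 CPM in PBS mice although CD45-positive cells had been gated out. Their share there of the counts outside mitochondrial ribosomal RNA was 0.0358 ± 0.0361% with NRG1 and 0.0225 ± 0.00974% with PBS (n = 3, two-sided exact permutation p = 0.8), and it ranged from 0.00863% to 0.0768% between NRG1 mice. Markers of goblet cells took 0.396 ± 0.172% of the counts outside mitochondrial ribosomal RNA in Lgr5neg cells with NRG1 and 0.827 ± 0.204% with PBS, with no overlap between the mice (exact permutation p = 0.1, the smallest possible).

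Of 15045 genes, 258 were fully separated between NRG1 and PBS mice in the same direction in all 4 populations, 107 higher and 151 lower. Among the falls were Trmt61a with a mean log2 change of -1.82 (chromosome 12, 111678105 to 111683902), Car4 at -1.50 and Pex11a, a peroxisomal division factor, at -1.36. Among the rises were Slc1a2, a glutamate transporter, at 1.44, Pik3r3 at 1.21, Trp53inp1 at 1.12, Cenpa at 0.90, the mitotic kinase Aurka at 0.89 and Erbb3 at 0.58. These names were chosen after their values were seen.

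The other splits of the 6 mice gave 0 to 13 such genes, so 1 of 10 splits reached 258, and 10 splits are too few for a share under 0.05. The genes that rose had a median GC content of 45.0% and those that fell 52.4%, against 49.4% for all genes. With the GC and length trend of each library removed, 265 genes were separated, 174 of them in both sets, so that trend does not explain their number. The 258 genes lay on 21 chromosomes with at most 21 on 1 of them. A response of the whole crypt to NRG1 is a possible explanation, and a difference between the treatment groups in handling or library preparation that the labels do not record remains open too.

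A further hypothesis was that NRG1 may move each population towards the stem cell end of the differentiation path. The NRG1 change was set against a PBS difference between a population nearer to and another further from the stem cell end. On Lgr5med minus Lgr5neg the slope was 0.0119 in Lgr5high cells. On Lgr5high minus Lgr5neg it was 0.0598 in Lgr5med and 0.0742 in Lgr5low cells. On Lgr5high minus Lgr5low it was 0.0864 in Lgr5neg cells. Slopes on different axes cannot be ranked by size, as Lgr5med cells gave 0.156 on Lgr5high minus Lgr5low. From Lgr5high to Lgr5neg cells, the highest absolute slopes of other splits were 0.0435, 0.0609, 0.0747 and 0.0681. A slope as large came from 6 of the other splits in Lgr5high, 1 in Lgr5med, 1 in Lgr5low and 0 in Lgr5neg cells. The bound set beforehand read a slope above all other splits for the hypothesis and a smaller one against it. That bound was wrong in both directions, because 10 splits are too few for a share under 0.05, so the hypothesis stays open in all 4 populations.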
